A study of Mus musculus with 14 samples.

How the data were processed

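Bulk RNA from mouse tumours was measured in 14 libraries, made with the QuantSeq kit of Lexogen, which reads the 3' end of polyadenylated RNA. The labels give 2 mouse strains, written as NGS mouse and C57BI/6 mouse, and 2 treatments, vehicle and ACSS2i, an inhibitor of the acetyl-CoA synthetase ACSS2. It is unclear which strain the label NGS stands for, and its immune status was not given, so none was assumed. The tumour cell line, the inhibitor's dose and the length of treatment were not given in the sources used here. The series' design line names different Bmal1 status, but no label assigns a Bmal1 status to a library, so none was used.

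The deposited table holds raw whole-number counts per gene, one column per library, for 51789 Ensembl genes. Per the submitters' processing notes the authors used genome build mm10, RSEM 1.2.3 and DESeq2, with no role stated for each; the aligner, the annotation release and any filter were not given in the sources used here. RSEM estimates may have been rounded to whole counts by the authors. Symbols, positions and gene types came from the GENCODE M21 annotation of mm10, which matched 51596 of the genes and left 193 without a symbol. The genes encoded by the mitochondrial genome are not in the table.

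Counts were used as deposited. Library totals ran from 2.85 to 4.7 M in the NGS strain and from 17.6 to 20.3 M in the C57BI6 strain, so the depth followed the strain. Counting alone understates the error: pairs of libraries of the same group differed by 6.62 to 25.4 times the chi-square per degree of freedom that counting gives. A group with no count of a gene allows up to 3 counts, a floor of 0.218 CPM (counts scaled to the library total) in NGS vehicle, 0.27 in NGS ACSS2i, 0.043 in C57BI6 vehicle and 0.0395 in C57BI6 ACSS2i. The sources describe no molecular identifiers, so intervals and floors cover counting error only.

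Libraries were grouped by strain and treatment as labelled. Genes were kept by edgeR's filterByExpr, which left 17294, scaled by TMM and tested with the edgeR quasi-likelihood test in 1 model of all 4 groups, which share an estimate of the spread (common biological coefficient of variation 0.236). The comparisons were ACSS2i against vehicle in each strain, the difference between those effects (C57BI6 minus NGS, the interaction), and C57BI6 against NGS in vehicle. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Replicate numbers were checked for pairing between the treatments by correlating the libraries' deviations from their group means. Equal numbers gave -0.137 to 0.155 in C57BI6 (others -0.268 to 0.349) and -0.002 to 0.095 in NGS (others -0.124 to 0.081). Pairing was not seen in C57BI6. It stays open in NGS, where replicate 1 of both groups had the highest sum of skin genes. The main fit had no block, and a block was an alternative. Log2 fold changes are given with the standard error of the model, and levels as mean CPM with the SD across libraries.

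Gene lists for metabolism, stress, proliferation, tumour stroma, immune cells and interferon responses, 43 lists with 971 entries, were tested with limma's camera at a preset correlation of 0.01 between genes. Of these, 40 lists with 5 or more measured genes were tested, and adjusted p-values run over those 40. Camera compares a list with all other genes; it was also run with a correlation estimated for each list. The named genes are Acss2, Acss1 and Acss3, and for each comparison up to 10 higher and 10 lower genes with the smallest p among those past the threshold, with a mean log2 CPM of 1 or more and no overlap between the groups. Predicted genes, clones and pseudogenes were left out of that rule; where fewer than 5 genes passed in a direction, the first 5 are named with their values, and up to 4 members with the smallest p stand for each list. Not every gene that these rules pick is reported here. The comparisons, lists, naming rule and main alternatives were fixed before the data were examined.

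The method was tested on simulated data, in which 100 genes per size of change, all with a mean of 2 CPM or more, were altered in counts drawn to match these libraries. The edgeR test found 69 of 100 genes changed 2-fold and 96 of 100 changed 4-fold in the C57BI6 comparison, with 13 of its 189 calls false. It found 42 and 82 in the NGS comparison (6 false of 134), 28 and 83 in the interaction (5 of 117), and 60 and 90 between the strains (4 of 161). Camera found the raised list in each of the 4 simulations and no other list. The simulated genes were drawn independently, so camera's false calls among correlated genes were not tested. Each gene was drawn with the same spread in both strains. The larger spread of the real NGS libraries, and the false calls it may bring, were therefore not tested either. Other splits of the real C57BI6 libraries gave up to 28 lists.

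Alternatives were the size factors of DESeq2, the DESeq2 test, limma voom with sample quality weights, no filter, a stricter filter, a fit of only the groups compared, replicate number as a block, leaving out each library in turn, an estimated correlation for camera, and fry. Alternatives chosen after seeing the data were offsets for the GC content of the last 500 bases of each gene, a skeletal muscle score as covariate, leaving out the 3 C57BI6 libraries richest in muscle RNA, thinning the C57BI6 counts to the NGS depth, and keeping only protein-coding genes whose 3' end shares no 50-base stretch with another gene. The list of 5 sex-linked genes was left out of the values reported here. The 2 of them that passed the filter stayed in the tests and counts. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.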

Results

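RNA was sequenced from 14 mouse tumours, 1 library each, in 4 groups. The strain labelled NGS gave 3 vehicle and 3 ACSS2i libraries, and the strain labelled C57BI/6 gave 4 of each. ACSS2 makes acetyl-CoA from acetate in the cytosol and nucleus, and the series title describes its inhibitors as acting on metabolism and immunity in triple negative breast cancer. Depth per library was 4.21 to 4.7 M counts in NGS vehicle, 2.85 to 4.04 M in NGS ACSS2i, 17.6 to 19.2 M in C57BI6 vehicle and 18.4 to 20.3 M in C57BI6 ACSS2i. The first principal component of log2 CPM, 60.5% of the variance, separated the strains. The second, 11.1%, set NGS ACSS2i replicate 2 apart at -114.8, with the other libraries between -37.7 and 55.6. Libraries of the same group had Spearman correlations of 0.936 to 0.989 across genes, and libraries of different strains 0.857 to 0.897.

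**Figure D1:**
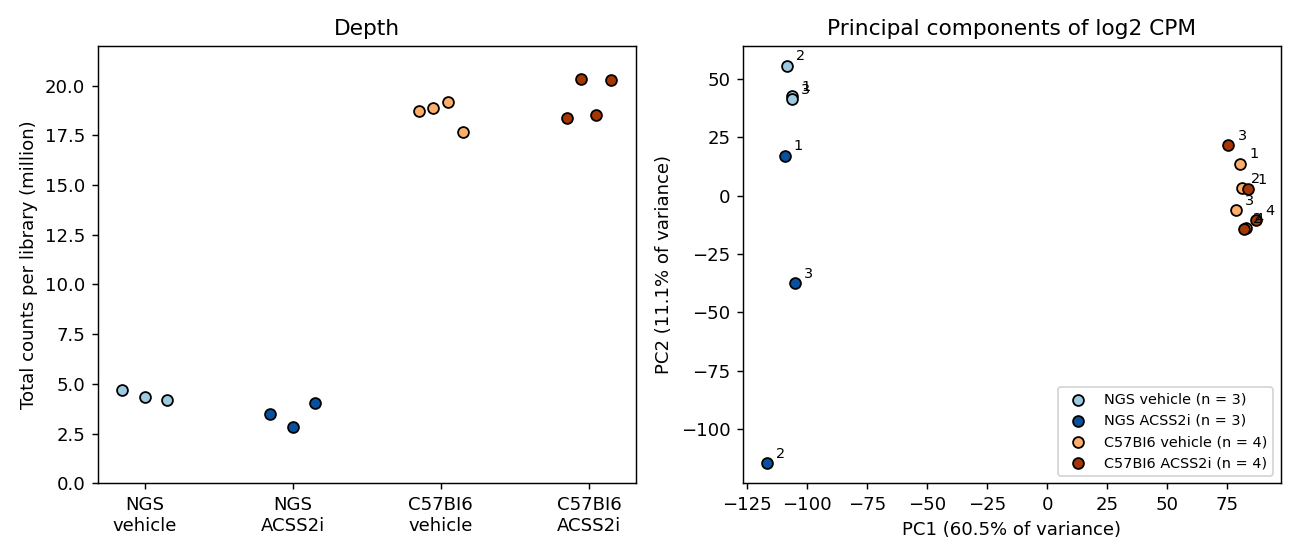
Total counts per library (left) and the first 2 principal components of log2 CPM (right) for the 14 libraries, coloured by group, with replicate numbers beside the points. NGS libraries held 2.85 to 4.7 M counts and C57BI6 libraries 17.6 to 20.3 M, and the first component (60.5% of the variance) separated the strains.

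The first comparison asked what the inhibitor changed in tumours of C57BI/6 mice, with 4 ACSS2i and 4 vehicle libraries. Several genes of cytotoxic lymphocytes and the interferon response, and the monocyte gene Ly6c2, were higher in the treated tumours. Ly6c2, a surface protein of inflammatory monocytes (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970, protein-coding), rose from 5.02 ± 1.18 to 45.2 ± 11.2 CPM (mean ± SD, n = 4 each), a log2 fold change of 3.17 ± 0.35 (SE, edgeR adjusted p = 0.00156). Ccl5, a chemokine that draws T cells and monocytes (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518, protein-coding), rose from 25.2 ± 8.04 to 98.1 ± 22.1 CPM (1.96 ± 0.26, adjusted p = 0.00344). Hmox1, the haem-degrading enzyme induced by oxidative stress (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589, protein-coding), fell from 45.9 ± 4.69 to 25.1 ± 2.53 CPM (-0.87 ± 0.12, adjusted p = 0.00344). The other named higher genes were Ms4a4c (1.94), Jaml (1.80), Ifi209 (1.45), Plac8 (2.28), Slfn1 (1.80), Ms4a6b (0.88), Ifit1bl1 (2.49) and Samhd1 (0.91), given as log2 fold changes, with adjusted p from 0.00156 to 0.00605. Jaml is an adhesion molecule of leukocytes, and Samhd1 a nucleotide hydrolase that restricts viruses. In each of these 11 genes the treated and vehicle libraries did not overlap, as the naming rule required. Of 17294 genes tested with edgeR, 45 were higher and 9 lower at adjusted p under 0.05, and 1613 genes (9.33%) had groups that did not overlap, where chance gives 1 in 35. Without NGS ACSS2i 1 or 2 the total of 54 became 98 or 122. It became 15, 17 or 20 without C57BI6 vehicle 2, 3 or 4. Without C57BI6 ACSS2i 1, 2, 3 or 4 it became 35, 15, 31 or 19.

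The remaining lower genes were few. Slc5a3, a myo-inositol transporter (log2 fold change -0.70 ± 0.12, adjusted p = 0.0196), Gdf15, a stress-induced cytokine (-1.71 ± 0.31, adjusted p = 0.0297), and Cxcl2, a chemokine for neutrophils (-1.20 ± 0.23, adjusted p = 0.0422), fell. Cxcl2 went from 36.7 ± 4.71 to 16.0 ± 7.26 CPM. Zfp503 was at -0.61 ± 0.12 and did not pass (adjusted p = 0.0519). The other 5 lower genes, chosen after their values were seen, were copies of 1 pseudogene family, Rps12-ps11 to Rps12-ps15, with identical values and 58 counts in vehicle against 2 in ACSS2i for Rps12-ps12. The call of Slc5a3 was lost without C57BI6 vehicle 2 or 4 or any 1 of the 4 C57BI6 ACSS2i libraries (adjusted p up to 0.105). That of Gdf15 was lost without C57BI6 vehicle 2, 3 or 4 or C57BI6 ACSS2i 1, 2 or 4 (up to 0.115). Cxcl2 was lost without NGS vehicle 2 or 3, NGS ACSS2i 3, any 1 C57BI6 vehicle library or C57BI6 ACSS2i 1, 2 or 4 (up to 0.2).

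By camera 5 lists of lymphocyte, interferon and class I genes were higher in the treated C57BI6 tumours, though most of their single genes did not pass. In the cytotoxic and natural killer cell list, 6 of 19 measured genes rose, 0 fell and 13 did not pass, 16 were higher when adjusted over the list alone, and the median log2 fold change was 1.62 (camera adjusted p = 1.86e-30). Gzmb, the protease that cytotoxic cells inject into their targets, rose from 1.77 ± 0.303 to 8.15 ± 3 CPM (2.20 ± 0.31, adjusted p = 0.019), and Klrc1, a receptor of natural killer cells, by 1.71 ± 0.25 (adjusted p = 0.0145). In the type I interferon list 7 of 32 genes rose and 25 did not pass, with 26 higher adjusted over the list alone and a median of 0.71 (camera adjusted p = 6.17e-37). Among them Mx1, an antiviral GTPase, rose by 1.51 ± 0.24 (adjusted p = 0.0145) and Oasl1 by 1.44 ± 0.24 (adjusted p = 0.0196). In the interferon gamma list, of which 7 genes also stand in the class I list, Irgm2 and Fcgr4 of 32 genes rose. Of them all, 26 were higher adjusted over the list alone, with a median of 0.91 (camera adjusted p = 1.59e-34). In the list for antigen presentation by class I molecules, H2-Q6 (1.41 ± 0.23, adjusted p = 0.0183) and H2-Q7 (1.49 ± 0.26, adjusted p = 0.0292) of 22 genes rose, with 12 higher adjusted over the list alone and a median of 0.43 (camera adjusted p = 1.05e-18). The T cell checkpoint list had 0 of 12 genes past the test and 9 adjusted over the list alone, with a median of 1.13 (camera adjusted p = 1.25e-10). Its summed level did not rise, with 302 ± 8.03 CPM in C57BI6 ACSS2i and 309 ± 58.1 CPM in C57BI6 vehicle. The median thus does not describe its most abundant genes. These 5 lists also passed with a correlation estimated per list (adjusted p = 0.0372 each).

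Single libraries decided several of these gene calls. Mx1 was lost without C57BI6 vehicle 2 or C57BI6 ACSS2i 2 (adjusted p up to 0.0706). Oasl1 was lost without C57BI6 vehicle 2 or 4 or C57BI6 ACSS2i 2, 3 or 4 (up to 0.0763), Klrc1 without C57BI6 vehicle 2, 3 or 4 or C57BI6 ACSS2i 2 or 4 (up to 0.0796), and Gzmb without C57BI6 vehicle 2, 3 or 4 or C57BI6 ACSS2i 4 (up to 0.0876). H2-Q6 was lost without C57BI6 vehicle 2, 3 or 4 or C57BI6 ACSS2i 2 (up to 0.0796), and H2-Q7 without these or C57BI6 ACSS2i 4 (up to 0.0938). Irgm2 and Fcgr4, at adjusted p = 0.0468 and 0.0499, were each lost without 10 of the 14 libraries in turn, which include C57BI6 vehicle 2, 3 and 4 and all 4 C57BI6 ACSS2i libraries (up to 0.214).

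T cell and other leukocyte lists were also higher by camera in the treated C57BI6 tumours, but with few single genes past the test. In the T cell list 0 of 28 genes passed, 21 were higher adjusted over the list alone, all 28 had a positive log2 fold change and the median was 1.5 (camera adjusted p = 1.62e-24; adjusted p = 0.0535 with an estimated correlation). Ctla4, an inhibitory receptor of T cells, was at 2.72 ± 0.53 (adjusted p = 0.0701) and Cd2 at 2.12 ± 0.47 (adjusted p = 0.0929). In the macrophage and monocyte list Ly6c2 rose and 28 of 29 genes did not pass, with 9 higher adjusted over the list alone and a median of 0.33 (camera adjusted p = 1.44e-10; adjusted p = 0.0541 with an estimated correlation). The class II list had 0 of 14 genes past the test, 10 over the list alone and a median of 0.80 (camera adjusted p = 2.14e-11; adjusted p = 0.101 with an estimated correlation). The B and plasma cell list (0 of 14, 1 over the list alone, median 1.09, camera adjusted p = 1.15e-05) and the dendritic cell list (0 of 16, 5 over the list alone, median 0.47, camera adjusted p = 1.65e-05) had adjusted p = 0.104 and 0.128 with an estimated correlation. Summed over the T cell list, C57BI6 ACSS2i libraries held 145 ± 46 CPM and C57BI6 vehicle libraries 63.8 ± 14.1 CPM.

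**Figure D2:**
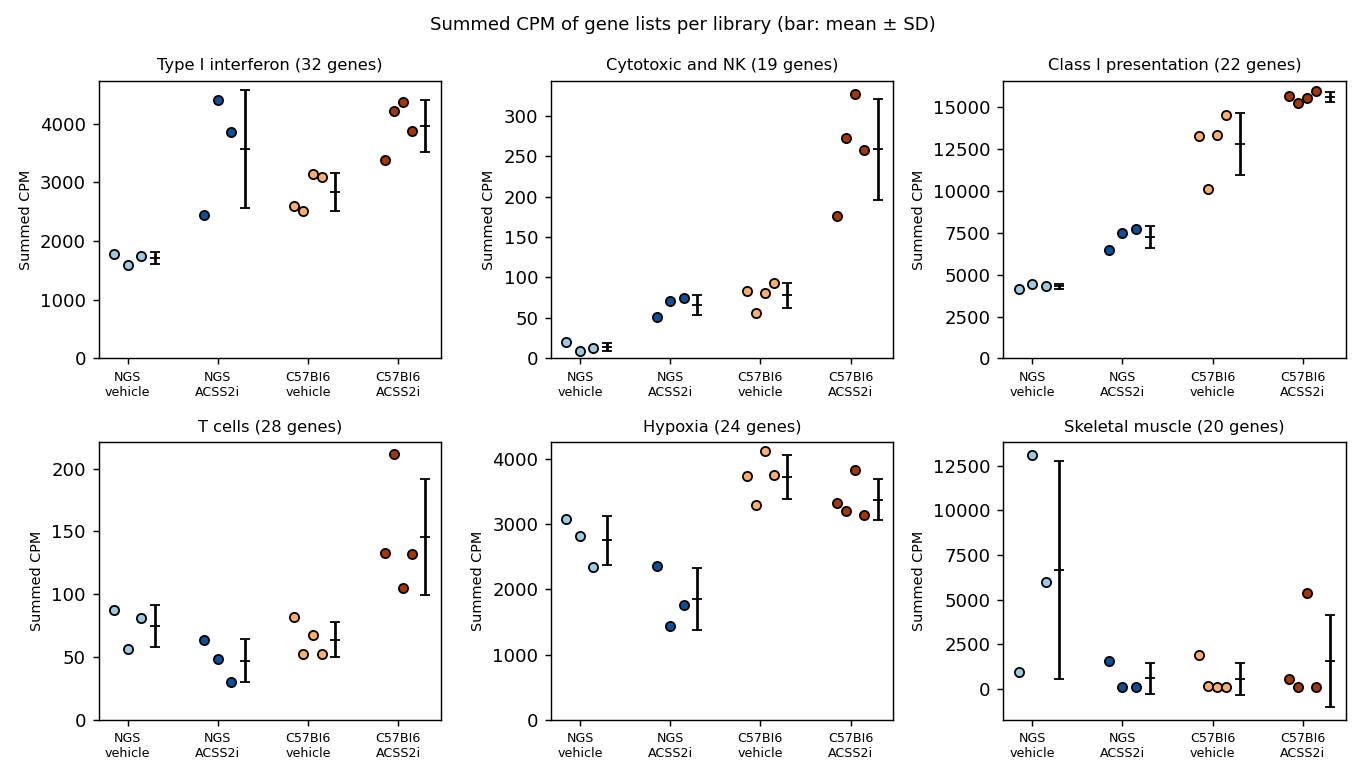
Summed CPM of 6 gene lists in each of the 14 libraries, with the mean and SD of each group as a bar. The cytotoxic and natural killer list sums to 258 ± 62.2 CPM in C57BI6 ACSS2i and 78.2 ± 15.3 CPM in C57BI6 vehicle, and the skeletal muscle list varies most within groups.

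Metabolic and stress lists moved less in C57BI6 tumours. The Nrf2 target list, antioxidant genes, had Hmox1 lower and 19 of 20 genes not passing, 2 lower adjusted over the list alone and a median of -0.26 (camera adjusted p = 3.68e-07; adjusted p = 0.0521 with an estimated correlation). The proliferation list had 0 of 41 genes past the test, 0 over the list alone, 39 positive log2 fold changes and a median of 0.14 (camera adjusted p = 4.22e-05; adjusted p = 0.471 with an estimated correlation). The ribosomal protein list had 0 of 42 and a median of -0.12 (camera adjusted p = 5.73e-07; adjusted p = 0.408 with an estimated correlation), and the cholesterol synthesis list 0 of 24 and -0.16 (0.00738; adjusted p = 0.552 with an estimated correlation). The NF-kB list had only Cxcl2 lower among 21 genes and a median of -0.15 (0.00539; adjusted p = 0.408 with an estimated correlation). The adipocyte list had 0 of 18 genes past the test and a median of 0.96, or 0.91 with Cidea, absent from vehicle, at its bound (2.64e-04; adjusted p = 0.48 with an estimated correlation). Another 10 lists passed camera at adjusted p = 0.0257 to 0.049: lysosome, erythrocyte and platelet, histone acetylation, immediate early, TCA cycle, oxidative phosphorylation, neutrophil, hypoxia and glycolysis lists, lower, and chemokines, higher. With an estimated correlation these had adjusted p = 0.191 to 0.587. The histone acetylation list mixes enzymes that add acetyl groups with enzymes that remove them, so it gives no direction for acetylation. The chemokine list held Ccl5, higher, and Cxcl2, lower, the latter also the only gene past the test in the neutrophil list. Each of these 10 lists was lost without any 1 of 3 to 12 libraries (adjusted p up to 0.808), C57BI6 vehicle 3 and C57BI6 ACSS2i 4 each ending 9 of the 10 calls. Cholesterol synthesis was lost without C57BI6 vehicle 2 or 3 or C57BI6 ACSS2i 4 (up to 0.333), proliferation (0.0877) and NF-kB (0.0711) without C57BI6 vehicle 4, and adipocytes without C57BI6 vehicle 2 (0.0635).

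None of the genes for the enzymes of acetate use passed the test in C57BI6 tumours. Acss2 (ENSMUSG00000027605, chromosome 2, 155517948 to 155585724, protein-coding) was at 2.82 ± 0.705 CPM in ACSS2i and 2.63 ± 0.334 CPM in vehicle (log2 fold change 0.10 ± 0.32, adjusted p = 0.994). Acss1, the mitochondrial enzyme, was at 0.61 ± 0.33 (adjusted p = 0.743) and Acss3 at -0.43 ± 0.47 (adjusted p = 0.931). The acetyl-CoA supply list (0 of 16 past the test, median -0.07, camera adjusted p = 0.609), the fatty acid synthesis list (0 of 23, median -0.05, 0.1) and the fatty acid oxidation list (0 of 21, median -0.04, 0.674) did not pass. Skeletal muscle genes, markers of another tissue, varied within both groups: Acta1, muscle actin, ran from 0.483 to 181 CPM in vehicle and from 0.545 to 938 CPM in ACSS2i, and the muscle list was at a median of 1.57 (camera adjusted p = 0.101). Without the 3 libraries richest in muscle RNA, 21 genes passed in place of 54.

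The second comparison made the same contrast in the strain labelled NGS, with 3 libraries per group. Of the genes on 3 lists, 27 of 32 type I interferon and 5 of 22 class I genes were higher in the treated NGS tumours, and 5 of 24 hypoxia genes were lower. With an estimated correlation none of these lists passed (adjusted p = 0.367 each). H2-K1, a class I heavy chain (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347, protein-coding), rose from 77.9 ± 17.8 to 293 ± 36.1 CPM (mean ± SD, n = 3 each), a log2 fold change of 1.91 ± 0.21 (SE, edgeR adjusted p = 0.00127). B2m, the light chain shared by class I molecules (ENSMUSG00000060802, chromosome 2, 122147686 to 122153083, protein-coding), rose from 1499 ± 50.3 to 3365 ± 417 CPM (1.17 ± 0.13, adjusted p = 0.00127). Slc2a1, the glucose transporter GLUT1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983, protein-coding), fell from 92.5 ± 21.4 to 33.5 ± 13.8 CPM (-1.46 ± 0.24, adjusted p = 0.0102). The other named higher genes were Ifi44 (1.98), Ms4a4c (2.33), Oasl2 (1.49), Rtp4 (1.45), Ccl5 (2.57), Zbp1 (1.34), Ube2l6 (1.63) and Bst2 (1.39), with adjusted p from 0.00127 to 0.00455. Zbp1 is a sensor of viral nucleic acid and Ube2l6 an enzyme that attaches Isg15 to proteins. The other named lower genes were Pfn2 (-1.86), Serpinb1a (-1.54), Cox7c (-2.23), Slc25a4 (-0.71), Bnip3 (-0.78), Snrpf (-1.62), Lig4 (-1.22) and Macc1 (-1.09), with adjusted p from 0.00395 to 0.0102. Cox7c is a subunit of cytochrome c oxidase, Slc25a4 the mitochondrial ADP/ATP carrier and Pfn2 an actin-binding profilin. The groups did not overlap in any of these 19 genes, as the naming rule required.

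With edgeR 228 genes were higher and 238 lower of 17294 in the NGS comparison, and 3249 genes (18.8%) had groups that did not overlap, where chance gives 1 in 10. The total of 466 became 174, 244 or 227 without NGS vehicle 1, 2 or 3, and 1743, 118 or 177 without NGS ACSS2i 1, 2 or 3. It became 300 without C57BI6 vehicle 3 and 293, 297, 292 or 289 without C57BI6 ACSS2i 1, 2, 3 or 4, whose spread enters the shared estimate. NGS libraries alone gave 9 genes. Among genes with a mean log2 CPM of 5 or more, the median SD of log2 CPM was 0.208 in NGS ACSS2i and 0.168 in NGS vehicle. In C57BI6 ACSS2i and vehicle it was 0.098 and 0.118. The shared estimate of the spread may thus understate the error in NGS and overstate it in C57BI6.

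The interferon, class I and macrophage lists were higher in NGS by camera with the preset correlation but not with an estimated one. In the type I interferon list 27 of 32 genes rose, 0 fell and 5 did not pass, all 32 were higher adjusted over the list alone, and the median was 1.34 (camera adjusted p = 4.16e-33; adjusted p = 0.367 with an estimated correlation). In the interferon gamma list 11 of 32 rose and 21 did not pass, with 19 higher and 1 lower adjusted over the list alone and a median of 1.17 (camera adjusted p = 5.5e-10; adjusted p = 0.609 with an estimated correlation). Cxcl10, a chemokine for activated T cells, rose by 1.67 ± 0.25 (adjusted p = 0.00575), Gbp3 by 1.81 ± 0.28 (adjusted p = 0.00746) and Igtp by 1.85 ± 0.34 (adjusted p = 0.0149; 0.0547 without NGS ACSS2i 2). In the class I list 5 of 22 rose and 17 did not pass, with 13 higher and 1 lower adjusted over the list alone and a median of 0.73 (camera adjusted p = 1.01e-08; adjusted p = 0.367 with an estimated correlation). Besides H2-K1 and B2m, these included Tap1, the peptide transporter (1.81 ± 0.28, adjusted p = 0.00733), and H2-D1 (0.82 ± 0.15, adjusted p = 0.0142). In the macrophage list Ly6c2 rose by 3.20 ± 0.46 (adjusted p = 0.00552) and 28 of 29 genes did not pass. In that list 7 were higher adjusted over the list alone, with a median of 0.35 (camera adjusted p = 2.64e-04, or 0.0569 without NGS vehicle 1; adjusted p = 0.609 with an estimated correlation).

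**Figure D3:**
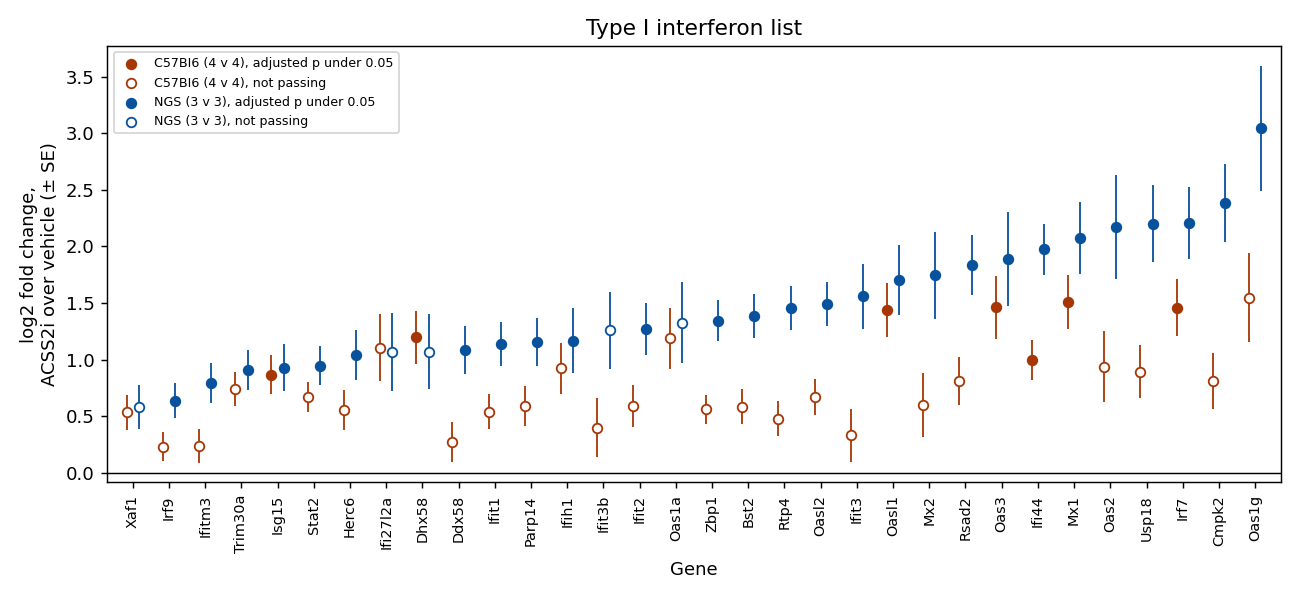
Log2 fold change of ACSS2i over vehicle, with its standard error, for the 32 genes of the type I interferon list in C57BI6 (4 against 4 libraries) and NGS (3 against 3), filled where edgeR adjusted p was under 0.05. All 32 genes lie above 0 in both strains, with medians of 0.71 and 1.34.

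The hypoxia and glycolysis lists were lower by camera with the preset correlation but not with an estimated one. In the hypoxia list 5 of 24 genes fell, 0 rose and 19 did not pass, 15 were lower adjusted over the list alone, and the median was -0.71 (camera adjusted p = 9.01e-11; adjusted p = 0.367 with an estimated correlation). Beside Slc2a1, Bnip3, a mitophagy receptor induced by low oxygen, fell from 136 ± 11.2 to 79.4 ± 11 CPM (-0.78 ± 0.12, adjusted p = 0.00746). Egln3, an oxygen sensor, fell by 0.69 ± 0.14 (adjusted p = 0.0182; up to 0.065 without NGS vehicle 2, NGS ACSS2i 2 or NGS ACSS2i 3). In the glycolysis list, 4 of whose genes also stand in the hypoxia list, 3 of 19 fell and 16 did not pass, with 6 lower adjusted over the list alone and a median of -0.32 (camera adjusted p = 1.18e-04; adjusted p = 0.609 with an estimated correlation). Eno1, the enolase of glycolysis, was one of them (-0.71 ± 0.15, adjusted p = 0.0278; up to 0.0849 without NGS vehicle 1 or 2 or NGS ACSS2i 2 or 3). The TCA cycle list had 0 of 22 genes past the test, 1 lower over the list alone and a median of -0.28 (0.0193; adjusted p = 0.609 with an estimated correlation). The ribosomal protein list had 3 of 42 lower, 6 over the list alone and a median of -0.11 (camera adjusted p = 0.0498, lost without any 1 of 11 libraries, among them NGS vehicle 2 and 3, with adjusted p up to 0.245; adjusted p = 0.775 with an estimated correlation). RNA of other tissues moved with these groups: the muscle list summed to 6670 ± 6110 CPM in vehicle and 575 ± 851 CPM in ACSS2i (median -3.78, 0 of 20 genes past the test, camera adjusted p = 1.39e-04; adjusted p = 0.775 with an estimated correlation), and Krt14, a keratin of skin, ran from 26 to 308 CPM in vehicle and from 5.98 to 66.3 CPM in ACSS2i. With the muscle score as covariate 27 genes passed in place of 466.

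**Figure D4:**
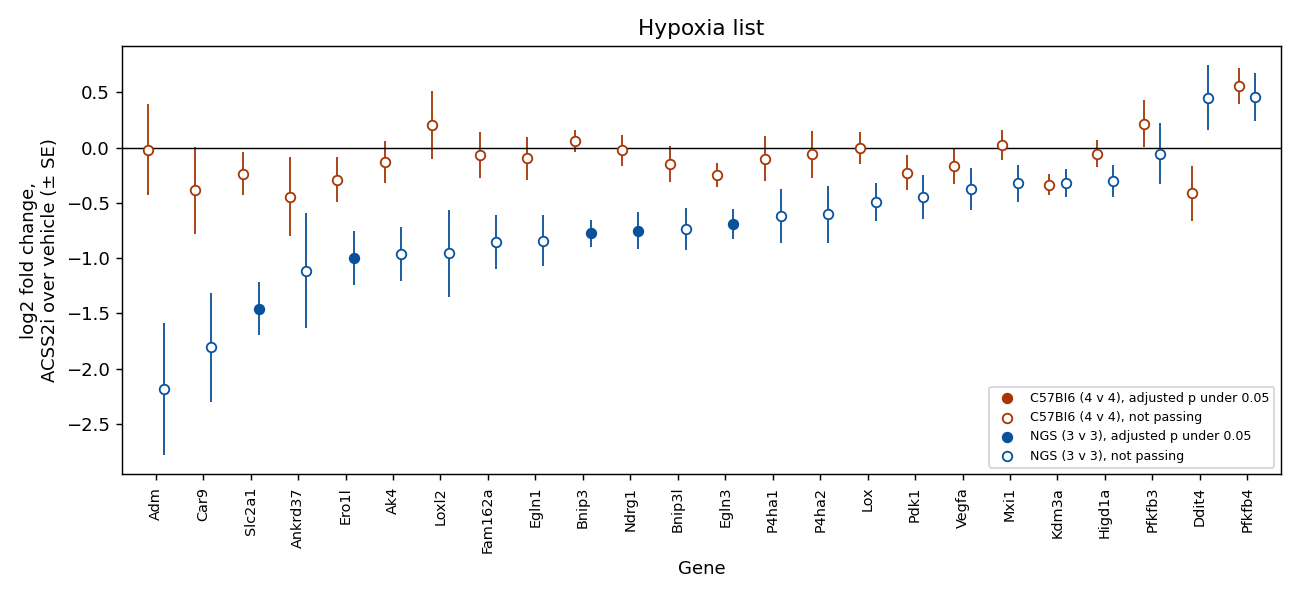
Log2 fold change of ACSS2i over vehicle, with its standard error, for the 24 genes of the hypoxia list in C57BI6 (4 against 4 libraries) and NGS (3 against 3), filled where edgeR adjusted p was under 0.05. In NGS 22 of 24 genes lie below 0 and 5 passed the test; in C57BI6 0 passed.

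Lymphocyte genes were near the counting floor in NGS tumours, a strain whose immune status the labels do not give. In the T cell list 14 of 28 genes had a group without any count and 15 were at or under the floor in both groups; Thy1, which fibroblasts also express, was the 1 gene past the test (-1.27 ± 0.31, adjusted p = 0.0431), lost without any 1 of 11 libraries, among them all 3 NGS vehicle libraries and NGS ACSS2i 2 and 3 (up to 0.142). No median is given for the list, as most of its genes were at or under the floor (camera adjusted p = 0.644). In the cytotoxic list Ccl5 alone of 19 genes rose, and 12 were at or under the floor in both groups (camera adjusted p = 0.177). The B cell (0 of 14, camera adjusted p = 0.182), checkpoint (0 of 12, 0.249), class II (1 of 14 higher, 0.282), dendritic cell (Bst2 of 16 higher, 0.182), neutrophil (1 of 16 lower, 0.182) and chemokine (4 higher and 1 lower of 33, 0.472) lists did not pass. The mast cell and eosinophil list had 0 of 8 genes past the test, 5 lower over the list alone and a median of -2.39 (0.00354; adjusted p = 0.767 with an estimated correlation).

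Acss2 was at 3.50 ± 1.76 CPM in ACSS2i and 3.21 ± 1.43 CPM in vehicle of the NGS strain (log2 fold change 0.10 ± 0.43, adjusted p = 0.936). Acss1 was at 0.64 ± 0.42 (adjusted p = 0.387) and Acss3 at -0.42 ± 0.79 (adjusted p = 0.81; 0.44 without NGS vehicle 3, 0.09 without NGS ACSS2i 2, -0.87 without NGS vehicle 2 and -1.25 without NGS ACSS2i 1). The acetyl-CoA supply list (1 of 16 lower, median -0.07, camera adjusted p = 0.654), fatty acid synthesis (3 of 23 lower, median -0.12, 0.438), fatty acid oxidation (2 of 21 higher, median 0.07, 0.249), cholesterol synthesis (0 of 24, median -0.19, 0.438) and proliferation (2 of 41 higher, median 0.10, 0.111) did not pass. Lpin1, a phosphatidate phosphatase of lipid synthesis, fell by 1.24 ± 0.21 (adjusted p = 0.0108). Hmox1 fell here too, by 0.79 ± 0.14 (adjusted p = 0.0149; 0.0507 without NGS vehicle 1).

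The third comparison asked whether the inhibitor's effect differed between the strains, as the C57BI6 effect minus the NGS effect. Pfn2 (ENSMUSG00000027805, chromosome 3, 57841895 to 57848079, protein-coding) went from 15.6 ± 2.64 to 4.31 ± 0.728 CPM with the inhibitor in NGS and from 3.94 ± 0.675 to 4.58 ± 0.59 CPM in C57BI6, a difference of effects of 2.07 ± 0.31 (edgeR adjusted p = 0.0394). Serpinb1a, an inhibitor of neutrophil proteases (ENSMUSG00000044734, chromosome 13, 32842092 to 32851185, protein-coding), went from 40.9 ± 0.952 to 14 ± 2.85 CPM in NGS and from 19.0 ± 2.55 to 24.6 ± 6.93 CPM in C57BI6 (1.91 ± 0.28, adjusted p = 0.0394). The 1 other gene past the test, chosen after its values were seen, was the pseudogene Amd-ps3, with 4 counts in NGS ACSS2i, 1123 in NGS vehicle, 6313 in C57BI6 vehicle and 6089 in C57BI6 ACSS2i (7.62 ± 0.74, adjusted p = 7.22e-04; 12.84 without NGS ACSS2i 3). Isg20 (1.26), Plac8 (2.48) and Lpin1 (1.41) on the higher side, and B2m (-0.96), Zgpat (-1.47), Ccnd2 (-0.83), Fbxw5 (-0.85) and Wnt5a (-0.74) on the lower side, did not pass (adjusted p from 0.0764 to 0.141). Acss2 (0.00 ± 0.49), Acss1 (-0.03 ± 0.55) and Acss3 (-0.01 ± 1.5) had adjusted p = 1. Without 1 library in turn Acss3 lay between -0.85 (without NGS vehicle 3) and 0.82 (without NGS ACSS2i 1). Of 17294 genes 3 were higher and 0 lower with edgeR, with 2383 at an unadjusted p under 0.05, 296 genes with DESeq2 and 0 with limma voom. The count was 62 without NGS ACSS2i 1, and 1 without NGS vehicle 3, NGS ACSS2i 2 or 3, C57BI6 vehicle 1, 3 or 4 or C57BI6 ACSS2i 1 or 2. Pfn2 was lost without any 1 library but NGS ACSS2i 1 (adjusted p up to 0.158), and Serpinb1a without any 1 of 10 libraries, among them all 3 NGS vehicle libraries (up to 0.16).

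By camera with the preset correlation 6 lists differed in their response between the strains, and none of them with an estimated correlation (adjusted p = 0.92 to 0.986). Type I interferon genes had a median difference of -0.64 over 32 genes (camera adjusted p = 9.15e-09), hypoxia genes a median difference of 0.57 over 24 genes (3.5e-08), muscle genes of 5.61 over 20 (1.67e-05), mast cell genes of 2.02 over 8 (0.00139), T cell genes of 1.66 over 28 (0.00726) and glycolysis genes of 0.27 over 19 (0.0228). No single gene of these lists passed over all genes with edgeR. Adjusted over the list alone, 10 type I interferon genes were lower, and 3 hypoxia, 4 muscle, 1 T cell and 1 glycolysis gene higher. For 14 of the 28 T cell genes an NGS group had no count, so the median of 1.66 does not measure a difference for them. The T cell call was lost without NGS vehicle 1 or NGS ACSS2i 3 (up to 0.137), and glycolysis without NGS vehicle 1 or 2, NGS ACSS2i 3, C57BI6 vehicle 2 or C57BI6 ACSS2i 3 (up to 0.217). The cytotoxic (0.121), class I (0.125), class II (0.106), checkpoint (0.237), interferon gamma (0.466), macrophage (0.966), acetyl-CoA supply (0.956), fatty acid synthesis (0.977) and proliferation (0.872) lists did not pass by camera.

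Genes past the test in both strains overlapped. Of the 45 genes higher in C57BI6 and the 228 higher in NGS, 21 were shared against 0.593 expected by chance, and of the 9 and 238 lower genes 1, Hmox1, was shared against 0.124. No gene passed in opposite directions. The comparisons have no library in common, though the model estimates 1 spread for both. Across all 17294 genes, which are not independent replicates, Pearson's r of the effects was 0.026 (p = 0.706) and Spearman's rho 0.116 (p = 0.114) in an exact permutation of the treatment labels within strains, with 1400 relabellings and a smallest possible p of 0.00286. Pearson's r changed sign without C57BI6 vehicle 1 (-0.046), C57BI6 ACSS2i 2 (-0.06) or C57BI6 ACSS2i 4 (-0.022). Spearman's rho stayed positive, from 0.076 (permutation p = 0.189) without C57BI6 vehicle 2 to 0.165 (permutation p = 0.02) without C57BI6 vehicle 4. With the stricter filter it was 0.18 (permutation p = 0.0857).

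The fourth comparison set vehicle tumours of C57BI6 (n = 4) against those of NGS (n = 3). Many class I, T cell, natural killer, neutrophil and NF-kB genes were higher in the C57BI6 tumours, and many fibroblast and skin genes and some endothelial, muscle and adipocyte genes lower. By camera these lists passed only with the preset correlation. B2m was at 7796 ± 1370 CPM in C57BI6 and 1499 ± 50.3 CPM in NGS, a log2 difference of 2.38 ± 0.13 (edgeR adjusted p = 3.55e-09). Gapdh, the glycolytic enzyme often used as a reference gene (ENSMUSG00000057666, chromosome 6, 125161715 to 125166467, protein-coding), was at 2573 ± 229 and 243 ± 42.4 CPM (3.40 ± 0.14, adjusted p = 1.58e-10). Peg10, an imprinted gene derived from a retrotransposon (ENSMUSG00000092035, chromosome 6, 4747306 to 4760517, protein-coding), was at 26.1 ± 3.3 and 243 ± 42.2 CPM (-3.22 ± 0.17, adjusted p = 2.72e-09). The other named higher genes were Unc13d (4.54), Chek2 (4.78), Snhg14 (7.27), Ccdc162 (8.10), Zfp280d (4.04), Churc1 (3.76), Caprin2 (3.93) and Vps8 (4.72), with adjusted p from 2.05e-11 to 2.35e-10, and Wdr31, with 5838 counts in C57BI6 and 1 in NGS, a ratio of 1150 (95% exact binomial interval 207 to 45500). The other named lower genes were Khdrbs3 (-4.72), Pdlim1 (-2.14), Adgrl2 (-2.66), Pogk (-2.87), Snhg18 (-2.71), Crip2 (-2.59), Tpm3-rs7 (-6.18), Cspg4 (-2.03) and Fau (-1.20), with adjusted p from 5.78e-09 to 1.08e-07. Chek2 is a DNA damage kinase, Unc13d acts in granule release, and Cspg4 marks pericytes. With edgeR 3245 genes were higher and 2421 lower of 17294, and 7014 (40.6%) had groups that did not overlap, where chance gives 2 in 35. Of the 3' ends of Gapdh, Churc1, Chek2, Tpm3-rs7 and Fau, 32.6%, 34.8%, 10.9%, 50% and 76.1% also occur in other genes, so their counts depend on how reads were assigned among copies. Strain and any separate processing run followed the same split of the libraries, so they cannot be told apart.

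By camera with the preset correlation 7 immune lists and the immediate early list were higher in the C57BI6 tumours, and none with an estimated correlation (adjusted p = 0.428 to 0.727). In the class I list 17 of 22 genes were higher, 1 lower and 4 did not pass, 18 were higher and 1 lower adjusted over the list alone, and the median was 1.61 (camera adjusted p = 6.36e-09). H2-K1 was higher by 3.41 ± 0.21 (adjusted p = 1.5e-08) and H2-Q4 by 4.44 ± 0.30 (adjusted p = 2.79e-08; 5.16 without NGS vehicle 2). The interferon gamma (24 of 32 higher, median 1.67, camera adjusted p = 2.11e-05), NF-kB (15 of 21, 1.02, 2.11e-05), type I interferon (19 of 32, 0.73, 9.34e-05), neutrophil (9 of 16, 1.13, 0.00275) and immediate early (12 of 20, 0.80, 0.00634) lists held no lower gene past the test. Adjusted over the list alone, 24, 16, 22, 9 and 14 of their genes were higher and 1 neutrophil gene lower. Cxcl2 was higher by 4.89 ± 0.37 (adjusted p = 1.19e-07) and Cxcr2, its receptor on neutrophils, by 2.61 ± 0.23 (adjusted p = 5.9e-07). In the cytotoxic list 16 of 19 genes were higher, also adjusted over the list alone, 9 had no count in NGS vehicle, and the median was 4.92, or 2.81 with these at their bound (camera adjusted p = 1.72e-04). Il2rb, a receptor chain for interleukin 2 and 15, was higher by 3.46 ± 0.42 (adjusted p = 1.91e-05). The T cell list had 16 higher and 2 lower of 28 (17 and 2 adjusted over the list alone), 11 with no count in NGS vehicle and a median of 3.16, or 1.70 with bounds (0.0357; lost without NGS vehicle 3, NGS ACSS2i 2 or C57BI6 vehicle 1 or 3, with adjusted p up to 0.0869).

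By camera with the preset correlation 5 lists of stroma and other tissues were lower in the C57BI6 tumours, and none with an estimated correlation (adjusted p = 0.428 to 0.727). The fibroblast and matrix list had 15 lower and 3 higher of 29 (16 and 4 adjusted over the list alone, median -0.47, camera adjusted p = 0.00124), with Lum, a collagen-binding proteoglycan, at -2.19 ± 0.24 (adjusted p = 5.69e-06) and Mmp3, a matrix protease, higher by 3.65 ± 0.29 (adjusted p = 1.79e-07). The endothelium and pericyte list had 9 lower and 1 higher of 26, also adjusted over the list alone (median -0.33, 0.00791). The skin list had 8 lower of 10 (10 adjusted over the list alone, median -8.62, or -8.51 with bounds, 0.0127; 0.0873 without NGS vehicle 1), the muscle list 4 of 20 (4, -3.80, 9.34e-05), and the adipocyte list 4 of 18 (10, -2.24, 0.00485; 0.126 without NGS vehicle 3). The macrophage list went both ways, with 6 higher and 5 lower of 29 (camera adjusted p = 0.613): Apoe was higher by 1.94 ± 0.21 (adjusted p = 4.62e-06), and Mrc1, a mannose receptor, was at -1.05 ± 0.13 (adjusted p = 2.4e-05). The B cell (4 of 14 higher, 0.423), class II (7 of 14 higher, 0.0593), checkpoint (4 higher and 1 lower of 12, 0.252), dendritic (4 higher and 2 lower of 16, 0.621), proliferation (6 and 7 of 41, 0.621), acetyl-CoA supply (3 of 16 lower, 0.0889), fatty acid synthesis (6 higher and 5 lower of 23, 0.405), fatty acid oxidation (1 and 4 of 21, 0.187) and cholesterol synthesis (2 and 2 of 24, 0.82) lists did not pass. Acss2 was at -0.30 ± 0.38 (adjusted p = 0.584), Acss1 at -0.92 ± 0.38 (adjusted p = 0.0778) and Acss3 at 0.99 ± 0.61 (adjusted p = 0.233; 1.84 without NGS vehicle 3 and 0.54 without NGS vehicle 2).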

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

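In this part the tests of depth, shared reads, GC content, the unusual library and muscle RNA, and the T cell sum without Thy1, were chosen after the results were seen; the tests with T cell and macrophage genes and the other splits of the libraries were chosen before.

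The type I interferon list was higher with the inhibitor in both strains by camera, by a median of 0.71 in C57BI6 (7 of 32 past the test) and 1.34 in NGS (27 of 32). With an estimated correlation the list passed in C57BI6 (adjusted p = 0.0372) and not in NGS (0.367). Its response differed between strains by camera (adjusted p = 9.15e-09) but not with an estimated correlation (adjusted p = 0.986) or fry (0.675). In NGS more T cells and a response within cells cannot be told apart. The T cell list summed to 47.1 CPM in treated and 74.7 CPM in vehicle libraries, but the fall lay in Thy1, which fibroblasts also express. The sums without it were 26.1 ± 11.5 and 23.6 ± 13.5 CPM, with Cd8b1 at 2.76 and 0.655 CPM and Trbc2 at 0.344 and 1.04 CPM. In C57BI6 a T cell score as covariate cannot settle whether more T cells are the whole cause. The T cell sums of treated (105 to 212 CPM) and vehicle libraries (52.5 to 82.1 CPM) did not overlap, so score and treatment are hard to separate. With the score the median was 0.83. The list score was 0.80 ± 0.19 before and 0.80 ± 0.37 after, with 7 members past the test before and 0 after, as the error grew. In NGS a macrophage score as covariate cannot settle whether more macrophages are the whole cause. The macrophage sums of treated (6610 to 6810 CPM) and vehicle libraries (5280 to 6410 CPM) did not overlap, so score and treatment are hard to separate. With the macrophage score the median was 1.07. The list score was 1.43 ± 0.22 before and 1.10 ± 0.29 after. Members past the test were 27 before and 0 after, with a smaller effect and a larger error. In C57BI6 the median fell to 0.41 with the macrophage score (0.80 ± 0.19 before and 0.41 ± 0.29 after). More macrophages and a response within cells thus cannot be told apart for that strain. Abundant macrophage genes went both ways in both strains and do not settle it. From vehicle to ACSS2i, Apoe was at 704 and 929 CPM, Lyz2 at 1117 and 994 and Spp1 at 987 and 641 in NGS. In C57BI6 they were at 2701 and 3483, 1334 and 1661, and 4035 and 3209 CPM. Neither the T cell nor the macrophage list shares a gene with the interferon list, and an effect of the inhibitor on interferon signalling may explain the pattern but was not tested.

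The strains differed in 5666 genes in vehicle tumours. The lower depth of the NGS libraries is argued against as the general cause, since 4276 genes passed after thinning the C57BI6 counts. Reads shared with near-identical copies are argued against for the 3705 of 12314 protein-coding genes without a shared 3' end that passed. For genes with a copy, shared reads and a difference in expression cannot be told apart. A test over 502 pairs of a gene and its copy settles nothing (median absolute difference 0.274 for the summed counts and 0.287 for the gene alone). The larger gene shared a median of 0% of its 3' end with the copy, and 298 copies showed no difference of their own. In the 5 pairs with opposite differences the median was 2.07 for the gene and 0.473 for the sum. These pairs were picked for opposite differences, so the sum tends to differ less whatever the cause, and they settle nothing either. Strain, a separate processing run and the tumours' own differences followed the same split and cannot be told apart. Any of these could contribute, and no label names a run.

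The hypoxia list was lower with the inhibitor in NGS by camera (median -0.71, 5 of 24 genes past the test) but not with an estimated correlation (adjusted p = 0.367). Its response differed between strains by camera (adjusted p = 3.5e-08) but not with an estimated correlation (adjusted p = 0.92) or fry (0.318). A trend with GC content is argued against as the whole cause, as the median was -0.68 with GC offsets (list score -0.76 ± 0.18 before and -0.73 ± 0.18 after; 5 and 4 genes past the test). So is the unusual library NGS ACSS2i 2, without which the median was -0.54 (score -0.51 ± 0.13; 2 genes past the test with 1 library fewer). Less muscle RNA in the treated libraries is argued against as the whole cause by a median of -0.6 with the muscle score as covariate (score -0.62 ± 0.21), though 0 genes passed with edgeR then, as the effect shrank and its error grew; Ttn, an abundant muscle gene, was at 2188 CPM in vehicle and 210 in ACSS2i, and the lists share no gene. A change in the oxygen supply or in the size of the tumours may also lie behind it and was not tested.

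Differences of the inhibitor's effect between the strains were found for Pfn2 (2.07), Serpinb1a (1.91) and Amd-ps3 (7.62), and, by camera with the preset correlation only, for the skeletal muscle (adjusted p = 1.67e-05), mast cell and eosinophil (0.00139), T cell (0.00726) and glycolysis (0.0228) lists, each at adjusted p = 0.986 with an estimated correlation. For 14 of the 28 T cell genes an NGS group had no count, so their difference between the strains was not measured. The T cell call was lost without NGS vehicle 1 or NGS ACSS2i 3 (up to 0.137), and glycolysis without any 1 of 5 libraries, NGS vehicle 1 or 2, NGS ACSS2i 3, C57BI6 vehicle 2 or C57BI6 ACSS2i 3 (up to 0.217). Single libraries stood far from the other 3 of their group in 24 of 364 tests by Dixon's ratio (critical value 0.829), where chance gives about 1 in 20. In C57BI6 vehicle, replicate 1 was highest for Klrc1 (6.42 CPM, next 4) and the muscle list (1880, next 145). Replicate 2 was highest for Tpsab1 (4.36, next 1.4), Mcpt4 (12.1, next 2.12) and the mast cell list (154, next 41.2), and lowest for Acss3 (1.45, next 2), H2-D1 (1150, next 1510) and Ccnd2 (1180, next 1360). Replicate 3 was highest for Slc2a1 (167, next 137), and replicate 4 for Zfp503 (157, next 139) and Krt14 (0.121, others 0). In C57BI6 ACSS2i, replicate 1 was highest for the fatty acid oxidation list (692, next 649) and replicate 4 for Zfp503 (101, next 91.5). Replicate 2 was highest for Samhd1 (234, next 191), Isg20 (49.6, next 43.7), Cspg4 (6.85, next 5.84) and the B cell list (752, next 226), and lowest for Mmp3 (1300, next 2340). Replicate 3 was highest for Ifi44 (127, next 88.8), Myh2 (76.8, next 0.113), Mb (29.2, next 1.13), Eno3 (146, next 89.5), Acacb (2.67, next 0.396) and the muscle list (5390, next 564).

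Other splits of the same libraries were fitted in the same way. The real split gave the most genes in C57BI6 (54, highest other 4, 1 of 35 splits) and between the strains (5666, highest other 7, 1 of 35). That share, 0.0286, is the smallest that 35 splits can give and was not adjusted over these tests, so chance is less likely but not excluded. The other splits mix the 2 groups, which raises the estimated spread, so their low counts do not measure how many genes chance would call. Chance also cannot be excluded for the interaction's genes (3, highest other 21, 6 of 100 drawn). There the split with 21 genes exchanged C57BI6 vehicle 1 with C57BI6 ACSS2i 3, the C57BI6 libraries highest in muscle genes. This points to a structure of the samples but was not tested further. Nor can chance be excluded for the number of lists. It was 26 in C57BI6 (highest other 28, 2 of 35), 6 in the interaction (highest other 25, 76 of 100) and 13 between the strains (highest other 22, 19 of 35). In NGS the 10 splits are too few for a share under 0.05: genes 466, highest other 21 (1 of 10), and lists 10, highest other 12 (3 of 10).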

How the results depend on the processing

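The GC offsets, the muscle score, the fit without the 3 muscle-rich C57BI6 libraries, the thinning and the genes without a shared 3' end were chosen after seeing the data. In C57BI6 the 54 genes became 332 with DESeq2, 429 with limma voom, 112 without a filter, 266 with only the 2 groups, 9 with a replicate block and 21 without the 3 muscle-rich libraries, and 15 to 122 without 1 library. In NGS the 466 genes became 1546 with DESeq2, 27 with limma voom, 9 with only the 2 groups, 254 with a block, 27 with the muscle score, and 118 to 1743 without 1 library. The 3 interaction genes became 296 with DESeq2, 0 with limma voom, 7 without a filter, 1 with the muscle score, 1 without the muscle-rich libraries, 1 after thinning, and 1 to 62 without 1 library; a fit of 2 groups cannot give this term. Between the strains 5666 became 3705 in genes without a shared 3' end, of which fewer were tested, and stayed at 4276 to 6348 otherwise and 4608 to 6715 without 1 library. Fewer samples account for part of the leave-one-out ranges. The libraries of NGS spread more than those of C57BI6, and the main fit shares 1 estimate of the spread. With only the 2 groups, C57BI6 gave more genes (266) than NGS (9), the reverse of the main fit. The numbers of genes or list members past the test therefore do not rank the strains' responses. Otherwise the cause was not tested.

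The 26 lists in C57BI6 became 17 with a stricter filter, 5 with an estimated correlation, 12 with fry and 16 to 25 without 1 library. The 10 in NGS became 0 and 3 with an estimated correlation and fry (9 to 12 without 1 library). The 6 of the interaction became 10 with a block, 0 with an estimated correlation and 0 with fry (4 to 8), and the 13 between strains 0 with an estimated correlation (11 to 19). The correlation of effects, 0.026, ran from -0.06 to 0.148 without 1 library. The named genes past the test were followed through every alternative that tested them, leaving out each library in turn included. Those that passed throughout were 5 of 25 in C57BI6, 5 of 48 in NGS, 0 of 3 in the interaction and 42 of 43 between strains. Not every gene was in every fit, such as that of genes without a shared 3' end. Depth limits the NGS groups, whose floor is 0.218 and 0.27 CPM against 0.043 and 0.0395 in C57BI6.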

Other observations

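Genes in this part were chosen after their values were seen, and no test was added for them. The 21 genes higher in both strains included Trim30c (1.84 in C57BI6 and 2.53 in NGS), P2ry14 (1.41 and 1.93), Epsti1 (1.21 and 1.00), Sp100 (1.03 and 1.06), Trex1 (0.88 and 1.19) and Isg15 (0.87 and 0.93). Il2rg, the receptor chain shared by several interleukins, rose from 22.7 ± 4.76 to 51.8 ± 11 CPM in C57BI6 (adjusted p = 0.0349) and from 2.23 ± 0.954 to 9.05 ± 3.67 CPM in NGS (adjusted p = 0.0182), the latter from 31 and 97 counts. Cd3e, a chain of the T cell receptor complex, had 0 counts in both NGS groups, 57 in C57BI6 vehicle and 217 in C57BI6 ACSS2i. Foxp3 had 0, 0, 45 and 139 counts, Gzma 0, 0, 71 and 364, and Gzmc 0, 0, 1121 and 3743, in the same order.

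The series' design line names Bmal1, whose gene is Arntl. Arntl was at 11.6 ± 2.29 CPM in C57BI6 vehicle, 11 ± 0.341 in C57BI6 ACSS2i, 5.83 ± 0.997 in NGS vehicle and 4.97 ± 0.968 in NGS ACSS2i. The circadian list had 0 of 17 genes past the test with the inhibitor in either strain (camera adjusted p = 0.726 in C57BI6 and 0.438 in NGS), and 5 higher and 6 lower between the strains (0.296).

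Lists not given above did not pass by camera. In C57BI6 these were heat shock (0.117), endothelium (0.213), EMT (0.251), fibroblasts (0.338), integrated stress (0.643), mast cells (0.643), p53 targets (0.726, with Gdf15 lower), mammary epithelium (0.848) and skin (0.937). In NGS they were adipocytes (0.0826), mammary epithelium (0.111), oxidative phosphorylation (0.177), erythrocytes (0.219), EMT (0.221), fibroblasts (0.221), skin (0.249), immediate early (0.28), NF-kB (0.282), histone acetylation (0.355), Nrf2 targets (0.433), integrated stress (0.436), heat shock (0.584), p53 targets (0.654), lysosome (0.732) and endothelium (0.801). Between the strains glycolysis (0.0519), lysosome (0.0593), chemokines (0.065), hypoxia (0.065), mast cells (0.0785), Nrf2 targets (0.0999), histone acetylation (0.487) and ribosomal proteins (0.82) did not pass.

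Fau and its near-identical copy Gm9843 differed between the strains in opposite directions: Fau was at 376 ± 27.8 CPM in C57BI6 vehicle and 863 ± 54.2 in NGS vehicle, Gm9843 at 942 ± 80 and 354 ± 32.4, and their sum at 1320 ± 91.3 and 1220 ± 54.3. Log2 fold changes followed the GC content of the last 500 bases of a gene with a Spearman correlation of 0.119 in C57BI6, 0.23 in NGS, -0.189 in the interaction and -0.006 between the strains over 9441 genes. Genes higher in NGS had a median GC content of 47.2%, genes lower 39.8% and all genes 43.8%. Krt10, a keratin of skin, ran from 6.28 to 312 CPM in NGS vehicle and from 4.53 to 7.22 CPM in C57BI6 vehicle.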
